A study of Mus musculus with 33 samples.

How the data were processed

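RNA of 33 mouse liver libraries was measured by RNA-seq. Per the labels' protocols, RNA came from fresh frozen liver with the Qiagen miRNeasy kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4 and RSEM 1.2.14 were used with the mouse genome build mm10; their settings and the gene annotation are not given in the sources used here. The deposited values are RSEM expected counts per gene, not normalised, of which 91.4% to 93.7% per library were whole numbers. RSEM divides reads that fit several genes among them, so genes with near-identical copies (the Mup, Saa, Orm, Cyp2c, Cyp3a, Cyp4a, Ugt2b, Gsta, Gstm, Sult2a and haemoglobin families) are uncertain one by one. The table held 19169 genes, all with a name, and every column was matched to a sample by its title. Gene positions are those of mm10 given with the table, from 1.

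Groups, sexes and replicate numbers came from the labels. Titles fall into 2 sets, numbered and numbered with a P, and carry an L code whose meaning is not stated. The labels do not say that each library is a separate mouse, so p-values measure the spread between these libraries. Sex labels matched the counts of Xist and Ddx3y in 33 of 33 libraries. No pair of libraries of 1 group was a repeat of the other: over 10922 genes and 128 pairs the lowest chi-square per gene was 28.7 (median 135). Intervals and floors given for genes with few counts cover counting error only, and 3 counts over the group is the floor.

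Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, filterByExpr by group, quasi-likelihood F test with robust=TRUE), with group, sex and title set in 1 model of all 33 libraries, which share 1 estimate of the spread. The filter left 14934 genes. Adjusted p-values are Benjamini-Hochberg values over these genes within a comparison, with a threshold of 0.05, and tests are two-sided. The 5 comparisons were KI against WT on each diet, ASK1i against control in each genotype, and the interaction. Log2 fold changes use a prior count of 0.125, and SE is the standard error of the log2 fold change. CPM values are those of edgeR's cpm function on TMM-normalised library sizes. There were 33 gene lists with 570 entries, of which 555 were in the table. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), with camera at an estimated correlation, and with fry. Their p-values were adjusted over the lists of a comparison. Members were counted over all genes tested and adjusted over the list alone. List scores are the mean log2 CPM of a list's members, compared by exact permutation tests.

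The groups, models, lists, named-gene rule and most alternatives were fixed before the data were examined. The rule named Nlrp3 and Map3k5 in every comparison. It took up to 10 of the largest rises and 10 of the largest falls among called genes with a mean of at least 1 CPM and an ordinary symbol (no Gm or Rik model, pseudogene, Mup copy, Xist or Y-linked gene). From each list with a called member it took up to 4 members with the smallest p, from a described list with none up to 2 as values, and where no gene was called the 5 smallest p as values. Eda2r, Islr in the diet comparisons, Nek7, Casp6, Casp9, Cyp17a1, Ntrk2, Moxd1 and Mup11 were named outside it, after their values were seen, as were genes repeated from 1 comparison in another. Some named genes are not reported here. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, other count filters, unrounded counts, robust=FALSE, other covariates, a block on the replicate number, subsets by group, title set and sex, each library left out in turn, and KI controls split between effects. Sex within genotype, L6 libraries alone and the combinations without KI ASK1i replicate 5 were chosen after seeing the data. The gene and list tests were tested on simulated data with the real means, library sizes and groups (14934 genes, 67, 67 and 66 of them changed at the 3 folds below). At folds of 1.5, 2 and 4 they recovered 53.7%, 71.6% and 93.9% of changed genes for KI against WT on control chow, 59.7%, 85.1% and 92.4% on the ASK1i diet, 64.2%, 85.1% and 97.0% for the inhibitor in WT and 26.9%, 71.6% and 90.9% in KI, with 0 in the wrong direction. False calls were 2.67%, 4.82%, 2.96% and 5.26% of calls.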

Results

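Polyadenylated liver RNA was sequenced in 33 libraries from mice of 2 genotypes on 2 diets. Knock-in (KI) mice carried a tamoxifen-inducible mutant allele of Nlrp3, the sensor protein of an inflammasome that matures interleukin-1 beta and triggers pyroptotic cell death. They were set beside wild-type (WT) mice. For 6 weeks the mice ate control chow or chow with GS-444217, a selective inhibitor of the kinase ASK1, which relays oxidative stress to stress-activated kinases and is encoded by Map3k5. The 2 diets are called control and ASK1i here. The design asks what the mutant allele does to the liver, and whether blocking ASK1 changes cell death and fibrosis in it. There were 10 WT control libraries (7 female, 3 male), 8 WT ASK1i (4 female, 4 male), 5 KI control (1 female, 4 male) and 10 KI ASK1i (5 female, 5 male). Total counts per library ran from 28099676 to 33572192 in WT control, 30212442 to 40008118 in WT ASK1i, 33754744 to 38584260 in KI control and 32245902 to 38393481 in KI ASK1i. Transcripts of Alb, the serum albumin of hepatocytes, made up 9.95% ± 0.943 (SD, n = 10) of counts in WT control, 9.55% ± 1.11 (n = 8) in WT ASK1i, 3.31% ± 0.849 (n = 5) in KI control and 4.38% ± 1.92 (n = 10) in KI ASK1i. The first principal component held 62.2% of the variance and separated the genotypes, with 1 exception. The library labelled KI ASK1i replicate 5, from a female mouse, lay at -59.2 among the WT libraries, whereas the other 9 KI ASK1i libraries lay from 54.8 to 103. It is kept in every value unless a sentence says that it was left out.

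**Figure D1:**
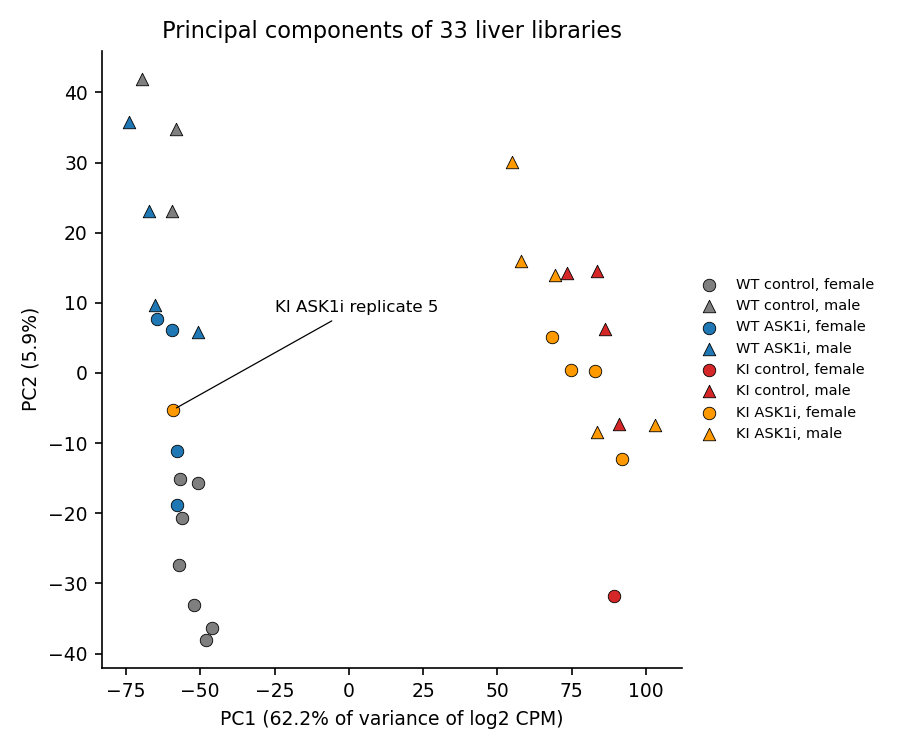
The first 2 principal components of log2 CPM of the 33 libraries (arbitrary units, with the percent of variance on each axis), 1 point per library, colour for group and shape for sex. The first component (62.2%) parts KI from WT libraries, with the KI ASK1i replicate 5 library at -59.2.

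Nlrp3 (Entrez gene 216799, mm10 chromosome 11, 59541585 to 59566956) was higher in KI liver than in WT liver on both diets. On control chow it averaged 3.03 ± 1.05 CPM (counts scaled to library size; SD, n = 10) in WT and 11.1 ± 3.45 CPM (n = 5) in KI, and it rose by 2.10 (SE 0.24) on the log2 scale (edgeR quasi-likelihood test, adjusted p = 3.64e-08), with all 5 KI control libraries above all 10 WT control libraries. On the ASK1i diet the means were 2.73 ± 0.492 CPM (n = 8) and 7.90 ± 2.66 CPM (n = 10), and the rise was 1.61 (SE 0.22) (adjusted p = 2.51e-07), with 9 of 10 KI ASK1i libraries above every WT ASK1i library. The exception was the library labelled KI ASK1i replicate 5, with 69 Nlrp3 counts. The gene-level counts do not separate the mutant from the wild-type transcript. Map3k5, which encodes the drug target ASK1 (Entrez gene 26408, mm10 chromosome 10, 19934526 to 20142750), was lower in KI. It fell by 0.74 (SE 0.17) on the log2 scale on control chow (from 38.0 ± 10.4 to 21.8 ± 2.80 CPM, adjusted p = 0.000407, 5 of 5 libraries). It fell by 0.61 (SE 0.14) on the ASK1i diet (from 37.9 ± 9.72 to 25.2 ± 5.22 CPM, adjusted p = 0.000292, 10 of 10 libraries below the WT ASK1i mean). No diet effect passed the test for either gene. In WT the log2 fold changes with the inhibitor were -0.02 (SE 0.22, adjusted p = 0.987, below the control mean in 7 of 8 libraries) for Nlrp3 and -0.01 (SE 0.14, adjusted p = 0.991, 3 of 8) for Map3k5. In KI they were -0.51 (SE 0.23, adjusted p = 0.4661, 10 of 10) and 0.12 (SE 0.16, adjusted p = 0.780, above the KI control mean in 7 of 10).

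**Figure D2:**
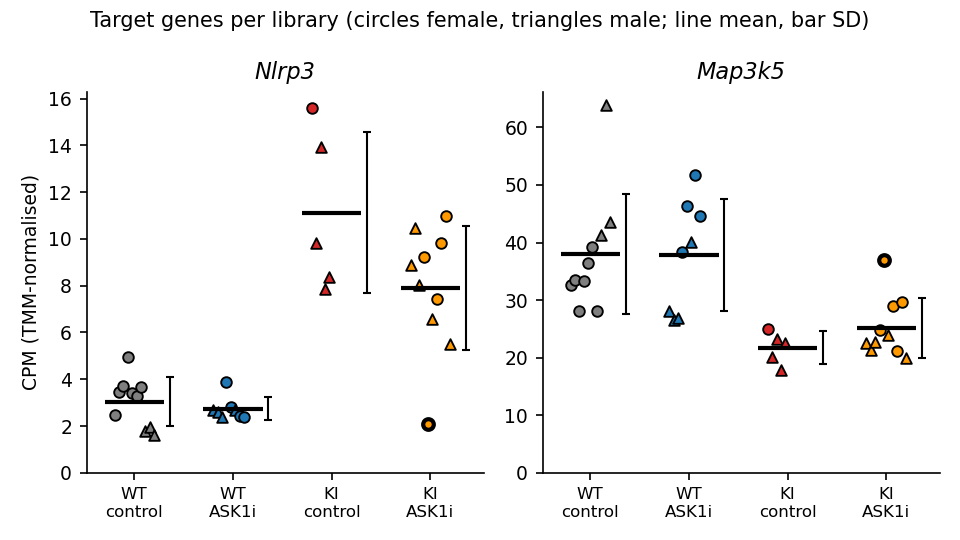
Nlrp3 and Map3k5 in TMM-normalised CPM per library in the 4 groups (circles female, triangles male, line mean, bar SD; a thick outline marks the library labelled KI ASK1i replicate 5). Nlrp3 averaged 3.03 ± 1.05 CPM in WT control and 11.1 ± 3.45 CPM in KI control, and Map3k5 38.0 ± 10.4 and 21.8 ± 2.80 CPM.

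On control chow, KI liver held far more transcripts of neutrophils, inflammatory macrophages and the acute-phase response than WT liver, and fewer of hepatocyte metabolism. S100a8, a calcium-binding protein abundant in neutrophils, rose from 2.36 ± 0.957 to 522 ± 261 CPM (SD, n = 10 and 5; log2 fold change 7.76, SE 0.68). Saa2, an acute-phase serum amyloid, rose from 24.0 ± 14.4 to 12096 ± 5381 CPM (log2 fold change 8.70, SE 0.68). Timp4, an inhibitor of matrix metalloproteinases, had the largest fitted rise among the named genes with counts in both groups, from 0.0333 ± 0.0855 to 166 ± 82.8 CPM (log2 fold change 12.01, SE 0.90). Alb fell by 1.54 (SE 0.20) on the log2 scale, and Cyp8b1, the sterol hydroxylase that sets the cholic acid share of bile acids, fell from 374 ± 175 to 3.34 ± 5.69 CPM (log2 fold change -7.17, SE 1.46). All 5 KI control libraries lay beyond all 10 WT control libraries for each of these 5 genes (edgeR adjusted p at most 0.00014). In all, 8466 of 14934 genes changed (56.7%), 4145 up and 4321 down, of which 2355 and 910 changed at least 2-fold. Stk33 and Itln1 had no counts in WT control and were at least 1009-fold and at least 790.0-fold higher in KI control, against a floor of 3 counts over the group. Slco1a1, an organic anion transporter of male liver, had no counts in KI control and was at least 2535-fold lower, though none of the 5 KI libraries lay below every WT control library. With the replicate 5 library left out 8926 genes changed, with the L code of the titles fitted in place of the title set 5103, and among numbered titles alone 6504. No L code held both WT control and KI control libraries, so the batch an L code may mark and the genotype could not be compared within it.

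All 16 neutrophil markers tested rose (16 adjusted over the list alone), with a median log2 fold change of 6.91 (camera adjusted p = 1.09e-10, and adjusted p = 0.279 with an estimated correlation). Among them were Mmp8, the neutrophil collagenase (7.11, SE 0.60), Mpo, myeloperoxidase (8.55, SE 0.92), the granule protein Ngp (8.45, SE 0.82), the chemokine receptor Cxcr2 (5.89, SE 0.52) and the integrin Itgam (4.50, SE 0.40). Of markers of monocyte-derived macrophages, 14 of 14 rose (14 adjusted over the list alone; median 3.57, camera adjusted p = 2.97e-09, and adjusted p = 0.279 with an estimated correlation). Examples were Chil3, a chitinase-like protein of activated macrophages (8.78, SE 0.75), and the endotoxin co-receptor Cd14 (5.38, SE 0.47). Kupffer cell markers rose in 13 of 13 members (13 adjusted over the list alone; median 1.69, camera adjusted p = 6.09e-07, and adjusted p = 0.279 with an estimated correlation). An example was the complement gene C1qb (2.07, SE 0.23). Of acute-phase genes 21 of 22 rose (21 adjusted over the list alone; median 2.41, camera adjusted p = 4.37e-10, and adjusted p = 0.279 with an estimated correlation). Examples were the siderophore-binding lipocalin Lcn2 (6.80, SE 0.61), Serpina3n (3.18, SE 0.29) and Orm1 (3.02, SE 0.29). The Saa and Orm copies resemble each other, so the split of reads among them is uncertain.

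Of the inflammasome and interleukin-1 list, 16 of 18 rose and 1 fell (16 and 1 adjusted over the list alone; median 1.74, camera adjusted p = 7.80e-07, and adjusted p = 0.279 with an estimated correlation). The decoy receptor Il1r2 (6.89, SE 0.66), the caspase Casp4 (3.62, SE 0.36) and pyrin, Mefv (3.34, SE 0.32), rose, while Nek7, a kinase that binds Nlrp3, fell (-0.47, SE 0.09). Of cytokines, chemokines and adhesion molecules 22 of 23 rose (23 adjusted over the list alone; median 3.05, camera adjusted p = 1.52e-09, and adjusted p = 0.279 with an estimated correlation). Examples were the chemokines Ccl6 (3.55, SE 0.32) and Cxcl2 (5.38, SE 0.54) and the inducible nitric oxide synthase Nos2 (7.21, SE 0.76). Lymphocyte markers moved apart. T and NK cell markers had 8 of 17 members higher and 1 lower (7 and 1 adjusted over the list alone; median 0.68, camera adjusted p = 0.0247, and adjusted p = 0.486 with an estimated correlation), with the costimulatory receptor Cd28 up (4.67, SE 0.45) and the T cell receptor kinase Zap70 down (-1.98, SE 0.27). B and plasma cell markers had 7 of 10 lower (7 lower and 1 higher adjusted over the list alone; median -2.08, camera adjusted p = 0.0294, and adjusted p = 0.519 with an estimated correlation). An example was Cd79a (-2.15, SE 0.47), beyond every WT control library in 4 of 5. Over the 33 left-out libraries the adjusted p of the T and NK list ran from 0.0195 to 0.0621, the highest without KI control replicate 1. That of the B cell list ran from 0.0127 to 0.0579, the highest without KI ASK1i replicate 5. The named genes of this and the preceding paragraph had adjusted p of at most 0.000265, and all but Cd79a lay beyond every WT control library in 5 of 5 KI control libraries. Erythroid markers, which also come from blood, had 4 of 8 lower (6 adjusted over the list alone; median -0.79, camera adjusted p = 0.0322, and adjusted p = 0.437 with an estimated correlation), with the carbonic anhydrase Car1 the most clearly changed (-5.74, SE 0.89). Camera adjusted p ran up to 0.0503 over left-out libraries, without KI control replicate 1P.

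Genes of fibrosis, cell death and division were also higher. Of fibrillar collagen and matrix genes 26 of 30 rose (26 higher and 1 lower adjusted over the list alone; median 1.28, camera adjusted p = 2.60e-08, and adjusted p = 0.279 with an estimated correlation). Examples were the metalloproteinase inhibitor Timp1 (5.06, SE 0.60), the collagen cross-linking enzyme Lox (3.21, SE 0.41) and the collagen Col5a2 (2.52, SE 0.29). Stellate cell and myofibroblast markers rose in 9 of 16 (9 adjusted over the list alone; median 0.67, camera adjusted p = 0.0144, and adjusted p = 0.437 with an estimated correlation). Examples were the intermediate filament Vim (2.16, SE 0.26) and the growth factor receptor Pdgfrb (0.92, SE 0.16). In the apoptosis and necroptosis list 15 of 22 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.68, camera adjusted p = 0.00119, and adjusted p = 0.299 with an estimated correlation). Ripk3, the kinase that starts necroptosis, rose (2.31, SE 0.25), whereas the caspases Casp9 (-0.36, SE 0.11, adjusted p = 0.00508) and Casp6 (-0.37, SE 0.13, adjusted p = 0.0172) fell. Over left-out libraries the adjusted p of Casp6 ran from 0.00699 to 0.0977, and its call ended without WT control replicate 8 or 2P or KI control replicate 4 or 1P. Cell cycle genes rose in 22 of 25 (22 adjusted over the list alone; median 2.83, camera adjusted p = 1.50e-08, and adjusted p = 0.299 with an estimated correlation). Examples were the replication helicase subunit Mcm5 (3.03, SE 0.38) and the topoisomerase Top2a (3.74, SE 0.51). AP-1 and immediate early genes rose in 9 of 16 (10 adjusted over the list alone; median 0.97, camera adjusted p = 0.0126, and adjusted p = 0.437 with an estimated correlation). Interferon-stimulated genes rose in 11 of 21 (11 adjusted over the list alone; median 0.59, camera adjusted p = 0.0220, and adjusted p = 0.566 with an estimated correlation). The nucleic acid sensor Zbp1 was at 2.16, SE 0.30. Fitting L code left 4 interferon genes higher (2 adjusted over the list alone; median 0.50). Casp9 lay below every WT control library in 4 of 5 KI control libraries and Casp6 in 3 of 5, and the other named genes of this paragraph lay beyond all of them in 5 of 5 (adjusted p at most 2.25e-05).

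Metabolic genes of the hepatocyte were lower. Of PPARA targets and fatty acid oxidation genes 23 of 24 fell (24 adjusted over the list alone; median -1.45, camera adjusted p = 1.09e-10, and adjusted p = 0.279 with an estimated correlation). Examples were the mitochondrial trifunctional protein Hadha (-1.16, SE 0.15) and the carnitine transferase Cpt2 (-1.45, SE 0.20). The microsomal fatty acid hydroxylases Cyp4a14 (from 3758 ± 2642 to 1.59 ± 1.40 CPM) and Cyp4a10 (from 3013 ± 1679.9 to 25.8 ± 31.9 CPM) fell too, though reads of these near-identical copies are hard to part. In the list of hepatocyte function 21 of 24 fell (21 adjusted over the list alone; median -0.84, camera adjusted p = 4.00e-06, and adjusted p = 0.279 with an estimated correlation). The thyroxine carrier Ttr was at -1.50, SE 0.20 and the ethanol-inducible Cyp2e1 at -2.29, SE 0.34. Bile acid synthesis and transport had 13 of 18 lower (13 adjusted over the list alone; median -0.98, camera adjusted p = 3.27e-05, and adjusted p = 0.279 with an estimated correlation). An example was the sterol hydroxylase Cyp27a1 (-1.10, SE 0.16). Lipogenesis genes fell in 12 of 22 (12 adjusted over the list alone; median -0.69, camera adjusted p = 0.0144, and adjusted p = 0.454 with an estimated correlation). Examples were malic enzyme Me1 (-1.63, SE 0.27) and the carbohydrate response factor Mlxipl (-1.55, SE 0.26). CAR and PXR targets, the drug-inducible enzymes, had 2 higher and 10 lower of 18 (2 and 10 adjusted over the list alone; median -0.78, camera adjusted p = 0.0166, and adjusted p = 0.486 with an estimated correlation), Cyp2c37 (-3.46, SE 0.63) and Aldh1a1 (-1.52, SE 0.32) among those that fell. Sex-dependent genes of either bias were lower. Female-biased genes had 2 higher and 11 lower of 18 (2 and 12 adjusted over the list alone; median -3.49, camera adjusted p = 0.00165, and adjusted p = 0.299 with an estimated correlation). Male-biased genes had 1 higher and 9 lower of 14 (1 and 9 adjusted over the list alone; median -2.69, camera adjusted p = 0.0193, and adjusted p = 0.486 with an estimated correlation). Cyp2c69 (-6.12, SE 0.88) and Cyp2c40 (-5.73, SE 0.82) fell in the first and Ugt2b1 (-3.17, SE 0.52) and Elovl3 (-5.36, SE 1.02) in the second, while Cyp17a1 (1.09, SE 0.34), Ntrk2 (2.28, SE 0.94) and Moxd1 (6.38, SE 1.59) rose. The adjusted p of Ntrk2 ran from 0.0169 to 0.429 over left-out libraries, with 12 of them ending its call, and 3 of 5 KI control libraries lay above the WT control mean for it. With sex fitted within genotype, chosen after seeing the data, male-biased genes had 0 higher and 3 lower (median -1.27) and female-biased genes 0 higher and 9 lower (median -2.78). With L code fitted they had 1 higher and 4 lower (median -1.66), and 1 higher and 10 lower (median -3.43). The named genes here had adjusted p of at most 0.0406, and the Cyp2c, Cyp4a and Ugt2b families share reads among copies.

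Of the 11 lists that camera did not pass on control chow 9 held changes in both directions. Cholesterol synthesis had 8 of 20 higher and 2 lower (6 and 2 adjusted over the list alone; median 0.53, camera adjusted p = 0.0926). The squalene epoxidase Sqle was up (1.32, SE 0.30, adjusted p = 0.000407), past every WT control library in 3 of 5 libraries. The list had 1 higher and 3 lower (median 0.22) with L code fitted and 13 higher with the replicate block, and passed camera without any of 3 libraries (adjusted p from 0.0242 to 0.237). The ASK1 cascade had 5 higher and 6 lower of 17 (5 and 6 adjusted over the list alone; median -0.05, mean 0.22, adjusted p = 0.843 with a downward direction in camera). NRF2 targets had 4 higher and 8 lower of 17 (4 and 9 adjusted over the list alone; median -0.31, mean 0.04, adjusted p = 0.398, downward). The unfolded protein response had 3 higher and 2 lower of 16 (3 and 2 adjusted over the list alone; median 0.11, adjusted p = 0.4656), heat shock and metallothionein genes 3 and 1 of 9 (3 and 1; median 0.12, adjusted p = 0.427). The metal-binding Mt1 was at 2.86, SE 0.45. AHR targets had 3 and 1 of 7 (3 and 1; median 0.28, adjusted p = 0.513). Cholangiocyte markers had 3 higher and 3 lower of 14 (3 and 3; median 0.28, adjusted p = 0.851), liver endothelial markers 7 and 4 of 18 (7 and 4; median 0.16, adjusted p = 0.589). Adipocyte markers had 1 and 2 of 3 (1 and 2; median -0.40, adjusted p = 0.513). Car3 was at -8.80, SE 1.66. The circadian clock had 0 and 4 of 18 (0 and 3; median -0.51, adjusted p = 0.206). The 1 pancreatic acinar marker tested did not pass (0.05, adjusted p = 0.988). In this comparison 22 of the 33 lists passed camera at a preset correlation of 0.01 and 0 passed with an estimated correlation (lowest adjusted p = 0.279). The test fry, which asks whether a list's genes move on balance 1 way, passed 25. Without the replicate 5 library camera passed 21 lists and the estimated correlation 1, the acute-phase response (adjusted p = 0.0411). The T and NK cell, B cell, stellate cell, interferon, CAR and PXR, erythroid and male-biased lists each lost their camera call in at least 1 other fit.

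**Figure D3:**
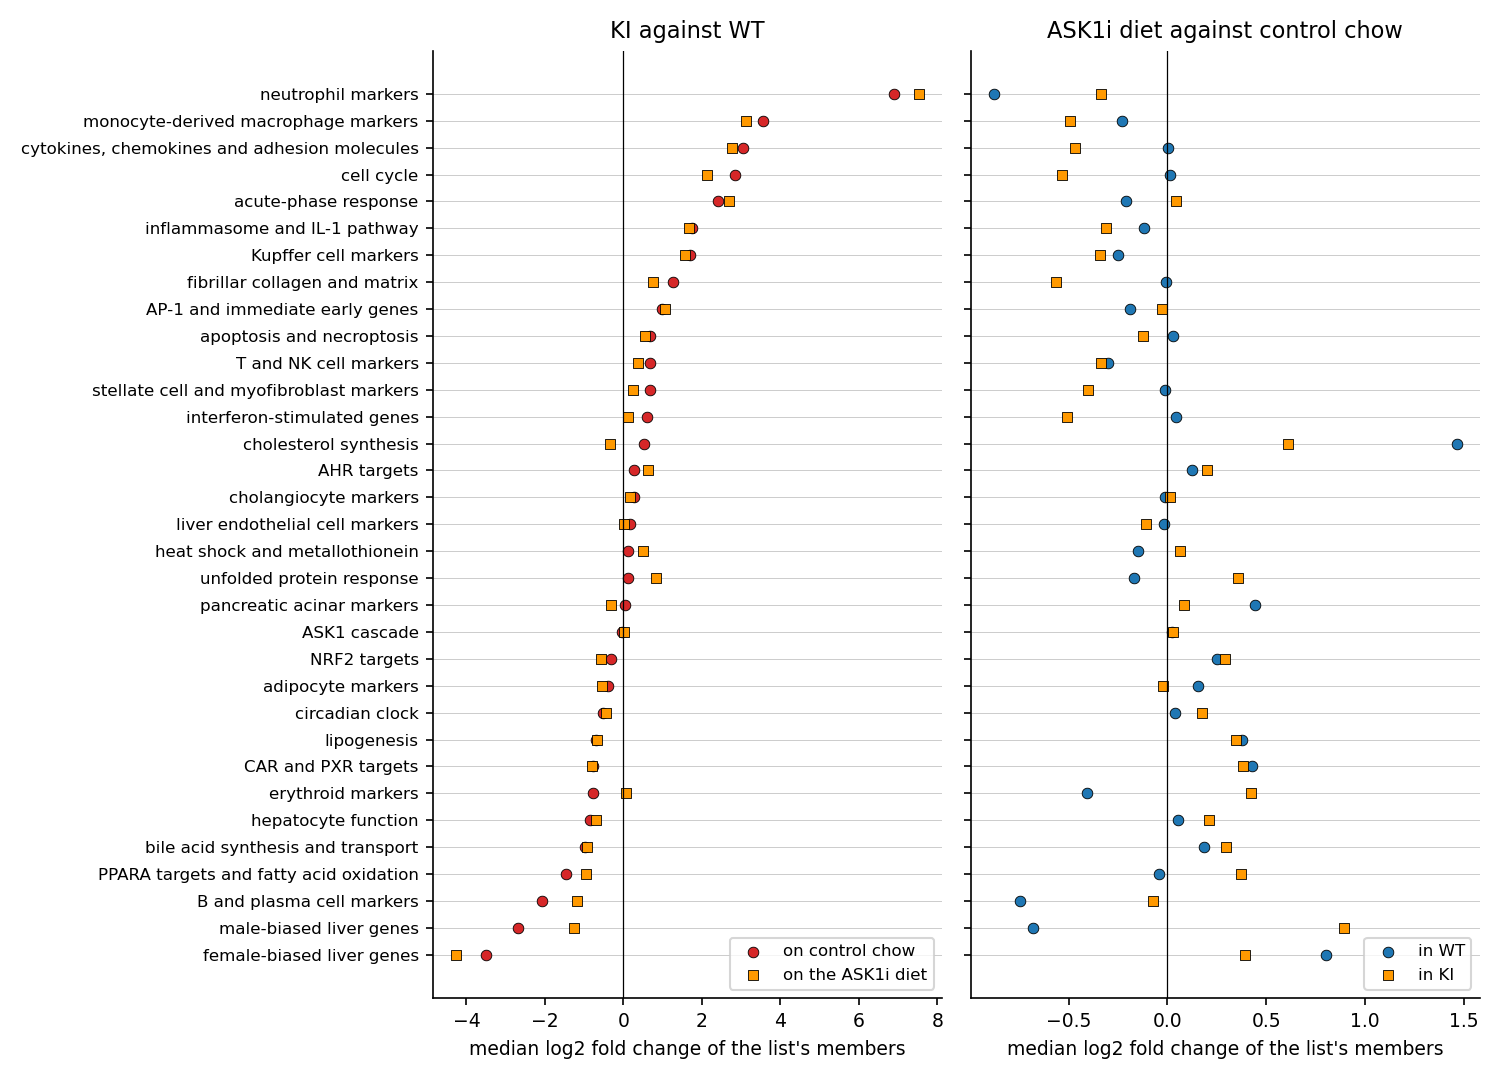
Median log2 fold change of the members of each fixed gene list, for KI against WT on each diet (left) and for the ASK1i diet against control chow in each genotype (right), 1 point per list and comparison. Neutrophil markers lay at 6.91 and 7.54 in the 2 genotype comparisons, and cholesterol synthesis at 1.46 in WT and 0.61 in KI in the 2 diet comparisons.

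On the ASK1i diet, KI liver again had more neutrophil, macrophage and acute-phase transcripts than WT liver. S100a8 averaged 1.15 ± 0.473 CPM (SD, n = 8) in WT and 426 ± 384 CPM (n = 10) in KI (log2 fold change 8.55, SE 0.74). Saa2 averaged 15.1 ± 3.06 and 12315 ± 6327 CPM (log2 fold change 9.53, SE 0.74) and Timp4 0.0552 ± 0.0671 and 101 ± 60.8 CPM (log2 fold change 10.70, SE 0.90). The neutrophil granule genes Mpo (11.09, SE 1.18), Camp (10.23, SE 1.08) and Ltf (10.11, SE 0.97) rose, and Alb fell by 1.23 (SE 0.16), Cyp8b1 by 5.21 (SE 1.00) and Hadha by 0.92 (SE 0.12) on the log2 scale. The largest falls included the female-biased Cyp3a41a (-8.28, SE 1.44) and Cyp2c69 (-6.54, SE 0.66), both from families with shared reads, and the keratin Krt23 (-4.94, SE 0.54). At least 9 of 10 KI ASK1i libraries lay past the WT ASK1i mean for each gene of this paragraph (edgeR adjusted p at most 5.22e-05). Of 14934 genes 8819 changed (59.1%), 4525 up and 4294 down, and 9435 without the replicate 5 library. Ctsg had 1 count over the WT ASK1i group and a ratio of 3582 (95% counting interval 643 to 141514), and Itln1 and Stfa2, with none there, were at least 383-fold and 369-fold higher. Genes that rose on both diets numbered 3560 and genes that fell on both 3432, where independent lists would share 1256 and 1242, and 5 changed in opposite directions. The log2 fold changes of the 2 comparisons, which share no library, had a correlation over genes of 0.926.

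By list, all 16 neutrophil markers rose (16 adjusted over the list alone; median 7.54, camera adjusted p = 3.36e-11, and adjusted p = 0.326 with an estimated correlation). So did all 14 markers of monocyte-derived macrophages (14; median 3.12, camera adjusted p = 4.44e-08, and adjusted p = 0.326 with an estimated correlation). All 13 Kupffer cell markers rose (13; median 1.58, camera adjusted p = 5.96e-07, and adjusted p = 0.326 with an estimated correlation). The scavenger receptor Cd163 was at 2.00, SE 0.22. Acute-phase genes rose in 21 of 22 (21 adjusted over the list alone; median 2.70, camera adjusted p = 2.43e-11, and adjusted p = 0.326 with an estimated correlation). Cytokines and chemokines rose in 21 of 23 (21; median 2.78, camera adjusted p = 1.31e-07, and adjusted p = 0.326 with an estimated correlation). The chemokine Cxcl14 was at 4.18, SE 0.47. Cell cycle genes rose in 22 of 25 (22; median 2.13, camera adjusted p = 8.32e-06, and adjusted p = 0.432 with an estimated correlation). Matrix genes rose in 19 of 30 (19 adjusted over the list alone; median 0.76, camera adjusted p = 0.00136, and adjusted p = 0.490 with an estimated correlation). Examples were the basement membrane collagen Col4a1 (1.36, SE 0.21) and Timp1 (5.63, SE 0.66). Stellate cell markers had 5 higher and 3 lower of 16 (5 and 3 adjusted over the list alone; median 0.26, camera adjusted p = 0.497), with Reln, a glycoprotein of quiescent stellate cells, lower (-0.44, SE 0.08). In the unfolded protein response 11 of 16 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.83, camera adjusted p = 0.0117, and adjusted p = 0.432 with an estimated correlation). Asparagine synthetase Asns (4.47, SE 0.47), the transcription factor Xbp1 (1.19, SE 0.13) and the chaperone cofactor Sdf2l1 (1.56, SE 0.32) rose. Of apoptosis and necroptosis genes 14 of 22 rose and 4 fell (14 and 5 adjusted over the list alone; median 0.54, camera adjusted p = 0.0268, and adjusted p = 0.465 with an estimated correlation), a call that ended without KI ASK1i replicate 1 (adjusted p from 0.00998 to 0.0546 over left-out libraries). AP-1 genes had 12 of 16 higher and 1 lower (14 and 1; median 1.05, camera adjusted p = 0.00393, and adjusted p = 0.408 with an estimated correlation). Fosl2 was at 1.76, SE 0.19. The plasma cell genes Igj (2.42, SE 0.41) and Mzb1 (1.45, SE 0.33) rose while 7 of the 10 B and plasma cell markers fell (2 and 7 adjusted over the list alone; median -1.19, camera adjusted p = 0.111, from 0.0465 to 0.195 over left-out libraries). Interferon-stimulated genes went both ways, with 5 higher and 6 lower of 21 (5 and 6; median 0.11, camera adjusted p = 0.998), the deconjugating protease Usp18 among the lower (-1.03, SE 0.22).

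PPARA targets fell in 20 of 24 (20 adjusted over the list alone; median -0.95, camera adjusted p = 1.17e-08, and adjusted p = 0.326 with an estimated correlation). Bile acid genes fell in 13 of 18 (13; median -0.93, camera adjusted p = 7.67e-05, and adjusted p = 0.326 with an estimated correlation). Hepatocyte function genes fell in 17 of 24, with 2 higher (17 and 2; median -0.70, camera adjusted p = 9.77e-05, and adjusted p = 0.337 with an estimated correlation). Female-biased genes fell in 14 of 18, with 2 higher (14 and 2; median -4.25, camera adjusted p = 8.05e-06, and adjusted p = 0.326 with an estimated correlation). Cholesterol synthesis, which was higher in part on control chow, had 6 of 20 lower and 0 higher here (6 adjusted over the list alone; median -0.34, camera adjusted p = 0.0651). The sterol sensor partner Insig1 was at -1.03, SE 0.22. Leaving out any 1 of 9 libraries brought that list under 0.05, and its adjusted p ran from 0.0239 to 0.195. In total 17 of 33 lists passed camera, 11 upward and 6 downward, 0 with an estimated correlation (lowest adjusted p = 0.326) and 23 by fry. The acute-phase list passed with an estimated correlation without the replicate 5 library (adjusted p = 0.0299). The camera call of the unfolded protein response ended with L code fitted and that of apoptosis genes in females alone. Median, mean and camera direction differed in sign for the ASK1 cascade, cholangiocyte, liver endothelial, interferon and erythroid lists, none of which passed. For each named gene of this and the preceding paragraph at least 8 of 10 KI ASK1i libraries lay past the WT ASK1i mean, and edgeR adjusted p was at most 0.000413. Among numbered titles alone 7035 genes changed.

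In WT mice genes of cholesterol synthesis were higher on the inhibitor diet. Mvd, mevalonate decarboxylase (mm10 chromosome 8, 122433596 to 122443422), rose from 10.2 ± 5.15 to 38.1 ± 9.58 CPM (SD, n = 10 and 8; log2 fold change 1.85, SE 0.23, adjusted p = 2.14e-05). Hmgcs1, which makes the precursor of mevalonate, rose from 214 ± 95.8 to 772 ± 180.0 CPM (log2 fold change 1.78, SE 0.23, adjusted p = 4.80e-05). The squalene synthase Fdft1 (1.44, SE 0.19) and the lanosterol demethylase Cyp51 (1.55, SE 0.22) rose as well. Mvd, Hmgcs1 and Fdft1 were above every WT control library in 8 of 8 WT ASK1i libraries and Cyp51 in 7. Of the 20 list members 19 rose over all genes tested and 20 adjusted over the list alone (median 1.46, camera adjusted p = 6.29e-52, and adjusted p = 0.00430 with an estimated correlation, and fry adjusted p = 2.14e-06). It was the 1 list of this comparison to pass with an estimated correlation. Within the 8 libraries of L code L6 (3 female and 1 male control, 1 female and 3 male ASK1i) the list median with sex in the fit was 1.10. The mean list score was higher on the inhibitor by 1.14 log2 units within sex, the largest of 16 splits (exact two-sided p = 0.0625, the lowest possible). In males alone the median was 0.98 (exact two-sided permutation p = 0.0571 over 35 splits), in females alone 1.63 (p = 0.00303 over 330 splits, exact permutation), and in numbered titles alone 1.41. Fewer members passed over all genes in these fits: 6 with L code fitted (median 1.11), 7 in numbered titles, 1 in females, 0 in males and 0 in L6, while 17 to 20 passed adjusted over the list alone.

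**Figure D4:**
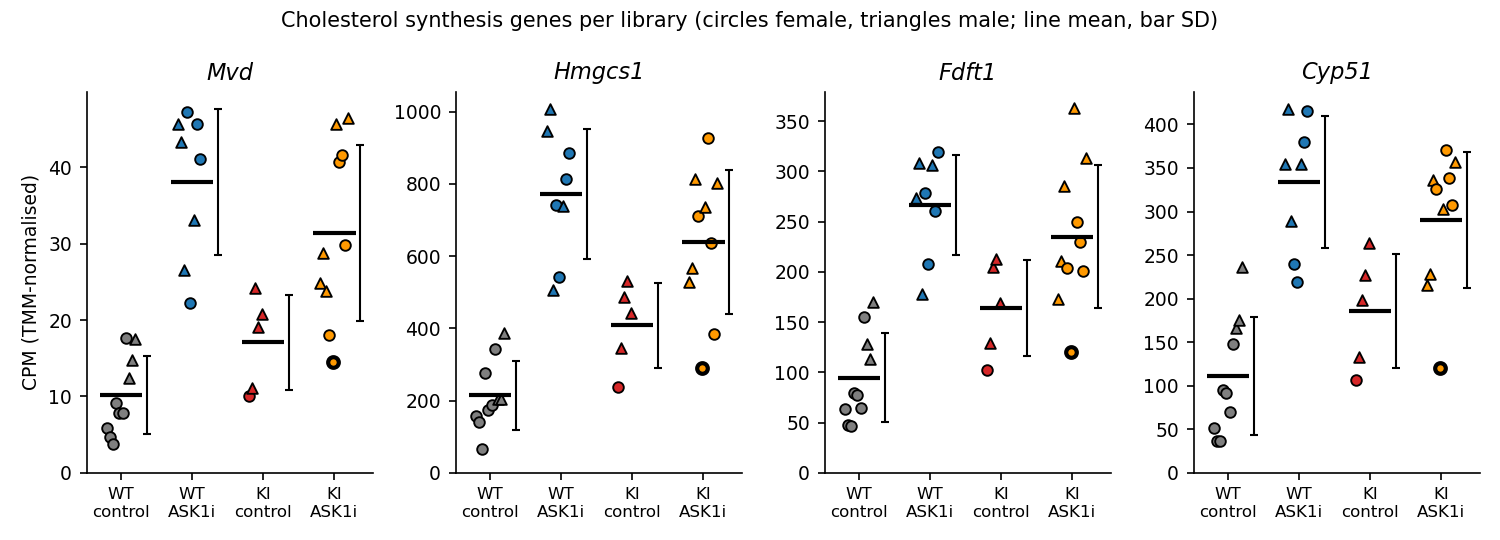
Mvd, Hmgcs1, Fdft1 and Cyp51 in TMM-normalised CPM per library in the 4 groups (symbols as in the Nlrp3 figure). Mvd averaged 10.2 ± 5.15 CPM in WT control and 38.1 ± 9.58 CPM in WT ASK1i.

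Other genes of detoxification and lipid metabolism rose in WT. Sult1e1, the oestrogen sulfotransferase, had the largest rise among the named genes, from 0.810 ± 0.883 to 13.2 ± 12.3 CPM (log2 fold change 4.00, SE 0.57, adjusted p = 0.000177, 8 of 8 libraries above the WT control mean), and averaged 211 ± 56.0 CPM in KI control. Of NRF2 targets 4 of 17 rose (7 adjusted over the list alone; median 0.25, camera adjusted p = 9.79e-06, and adjusted p = 0.0932 with an estimated correlation; fry adjusted p = 0.00224). They were the glutathione transferase Gsta1 (2.50, SE 0.49), whose reads are shared with near copies, the transporter Abcc4 (1.04, SE 0.15), the glucuronate-forming Ugdh (0.92, SE 0.20) and the quinone reductase Nqo1 (0.78, SE 0.20). Lipogenesis genes rose in 4 of 22 (6 adjusted over the list alone; median 0.38, camera adjusted p = 3.33e-06, and adjusted p = 0.292 with an estimated correlation; fry adjusted p = 0.0446). These were the desaturases Scd1 (1.43, SE 0.36) and Fads1 (0.62, SE 0.13), citrate lyase Acly (0.50, SE 0.12) and the fatty acid carrier Cd36 (0.60, SE 0.14). CAR and PXR targets rose in 2 of 18 (7; median 0.43, camera adjusted p = 0.000205, and adjusted p = 0.433 with an estimated correlation), Gsta1 and Gstm2 (0.84, SE 0.18). AHR targets rose in 2 of 7 (2; median 0.13, camera adjusted p = 0.0492, and adjusted p = 0.433 with an estimated correlation), Nqo1 and the hydrocarbon-inducible Cyp1a2 (1.26, SE 0.26). Of the 33 left-out libraries 10 ended that list's call (adjusted p from 0.0169 to 0.0895). The bile acid list had 1 member higher, Abcc4 (1 higher and 1 lower adjusted over the list alone; median 0.19, camera adjusted p = 0.0980, from 0.0272 to 0.245 over left-out libraries). The erythroid transcription factor Nfe2 (2.29, SE 0.43), the transporter Slc22a29 (1.95, SE 0.33) and the acetylcholine receptor subunit Chrna4 (3.08, SE 0.65) also rose. Adjusted p was at most 0.0380 for the genes of this paragraph, and at least 6 of 8 libraries lay above the WT control mean for each. The calls of Nqo1 (adjusted p from 0.0151 to 0.127), Scd1 (0.0245 to 0.161), Acly (0.0205 to 0.158) and Cd36 (0.00929 to 0.0647) ended without 10, 11, 12 and 2 single libraries, WT control replicate 1P among them for each.

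Few genes fell in WT on the inhibitor. The receptor Sorcs2 (from 3.72 ± 2.02 to 0.610 ± 0.405 CPM, log2 fold change -2.53, SE 0.51, adjusted p = 0.00694), the adipokine Serpina12 (-1.99, SE 0.42), Tor3a (-1.03, SE 0.22), the red cell anion exchanger Slc4a1 (-1.74, SE 0.35), the complement component C6 (-0.97, SE 0.24) and the male-biased pseudogene Serpina4-ps1 (-3.31, SE 0.81) fell, each past the WT control mean in at least 7 of 8 libraries (adjusted p at most 0.0333). The calls of C6 and Serpina4-ps1 each ended without any 1 of 7 libraries (highest adjusted p = 0.105 and 0.0975, both without WT ASK1i replicate 2P; lowest 0.00548 and 0.00270). Some immune lists lay lower in camera with few or no members called. Kupffer cell markers had 1 of 13 lower, C6 (1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00287, and adjusted p = 0.638 with an estimated correlation). Neutrophil markers had 0 of 16 called (0 adjusted over the list alone; median -0.88, camera adjusted p = 0.00159, and adjusted p = 0.638 with an estimated correlation), B and plasma cell markers 0 of 10 (0; median -0.74, camera adjusted p = 7.47e-05, and adjusted p = 0.433 with an estimated correlation). Acute-phase genes had 0 of 22 called (0; median -0.21, camera adjusted p = 0.0218, and adjusted p = 0.743 with an estimated correlation). Without the replicate 5 library 6 acute-phase genes were lower adjusted over the list alone. T and NK cell, monocyte-derived macrophage, inflammasome, cytokine and interferon lists did not pass (adjusted p = 0.0605, 0.106, 0.192, 0.346 and 0.864; medians -0.30, -0.23, -0.12, 0.00 and 0.04). The first passed without any of 4 libraries (0.0108 to 0.248) and the second without WT control replicate 2P (0.0412 to 0.245). Erythroid markers had 1 of 8 lower, Slc4a1 (1; median -0.41, camera adjusted p = 0.0220, and adjusted p = 0.435 with an estimated correlation). Female-biased genes lay higher with 0 called (4 adjusted over the list alone; median 0.80, camera adjusted p = 0.000205, and adjusted p = 0.433 with an estimated correlation). Male-biased genes lay lower with 1 called, Serpina4-ps1 (3; median -0.68, camera adjusted p = 0.000296, and adjusted p = 0.433 with an estimated correlation). The camera adjusted p of the acute-phase list ran from 0.000231 to 0.0944 over left-out libraries, losing its call without WT control replicate 8 or WT ASK1i replicate 2P. That of the erythroid list ran from 0.00691 to 0.0751, losing it without WT control replicate 8, 1P or 2P. No member of the matrix (median -0.01, adjusted p = 0.399), stellate cell (-0.01, 0.995), apoptosis (0.03, 0.542) or ASK1 cascade (0.02, 0.371) lists was called by edgeR or by camera, over all genes or adjusted over the list alone.

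In total 209 of 14934 genes changed in WT with the inhibitor, 169 up and 40 down, of which 45 and 19 changed at least 2-fold. Of 33 lists 12 passed camera, 6 in each direction, and 3 passed fry. The B cell, acute-phase, erythroid, female-biased, male-biased, AHR and CAR and PXR lists each lost their camera call in at least 1 other fit. Median, mean and camera direction differed in sign for the stellate cell, cytokine, apoptosis, bile acid, cell cycle, cholangiocyte, interferon and circadian lists, none of which passed. The count depended on single libraries. It was 136, 137 and 101 without WT control replicates 1, 3 and 1P, 105 and 109 without WT ASK1i replicates 1P and 2P, and 375 without KI ASK1i replicate 5, which enters the shared estimate of the spread. It was 23 with L code fitted, 19 among numbered titles alone, and 0 in edgeR within L6, where 962 genes had an unadjusted p under 0.05. DESeq2 called 365 and limma-voom 209 over all libraries.

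In KI mice 8 genes were lower with the inhibitor and 0 were higher, and 3 of the 8 were members of the matrix list. Lum, the collagen-binding proteoglycan lumican (mm10 chromosome 10, 97565501 to 97572703), fell from 18.8 ± 4.54 to 9.85 ± 2.90 CPM (SD, n = 5 and 10; log2 fold change -0.97, SE 0.18, adjusted p = 0.0306), against 8.14 ± 1.34 CPM in WT control. Bgn, the proteoglycan biglycan (mm10 chromosome X, 73483635 to 73495936), fell from 161 ± 45.9 to 109 ± 23.0 CPM (log2 fold change -0.65, SE 0.12, adjusted p = 0.0306). Fbn1, the microfibril protein fibrillin (mm10 chromosome 2, 125300594 to 125507993), fell from 11.7 ± 3.30 to 6.50 ± 1.97 CPM (log2 fold change -0.89, SE 0.18, adjusted p = 0.0405). Pcolce, which enhances procollagen cleavage (mm10 chromosome 5, 137605107 to 137611404), fell by 0.77 (SE 0.14) on the log2 scale (adjusted p = 0.0337). Col14a1, a fibril-associated collagen (mm10 chromosome 15, 55307750 to 55520803), fell by 0.70 (SE 0.14) (adjusted p = 0.0405). The other 3 were the Ras GTPase-activating protein Rasa4 (-0.78, SE 0.15), the septin Sept8 (-0.47, SE 0.09) and Eda2r, a receptor of the tumour necrosis factor family (-1.62, SE 0.29), named after its values were seen, with adjusted p from 0.0306 to 0.0405. All 10 KI ASK1i libraries lay below the KI control mean for each of the 8 genes, and for Lum, Pcolce and Sept8 below every KI control library.

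**Figure D5:**
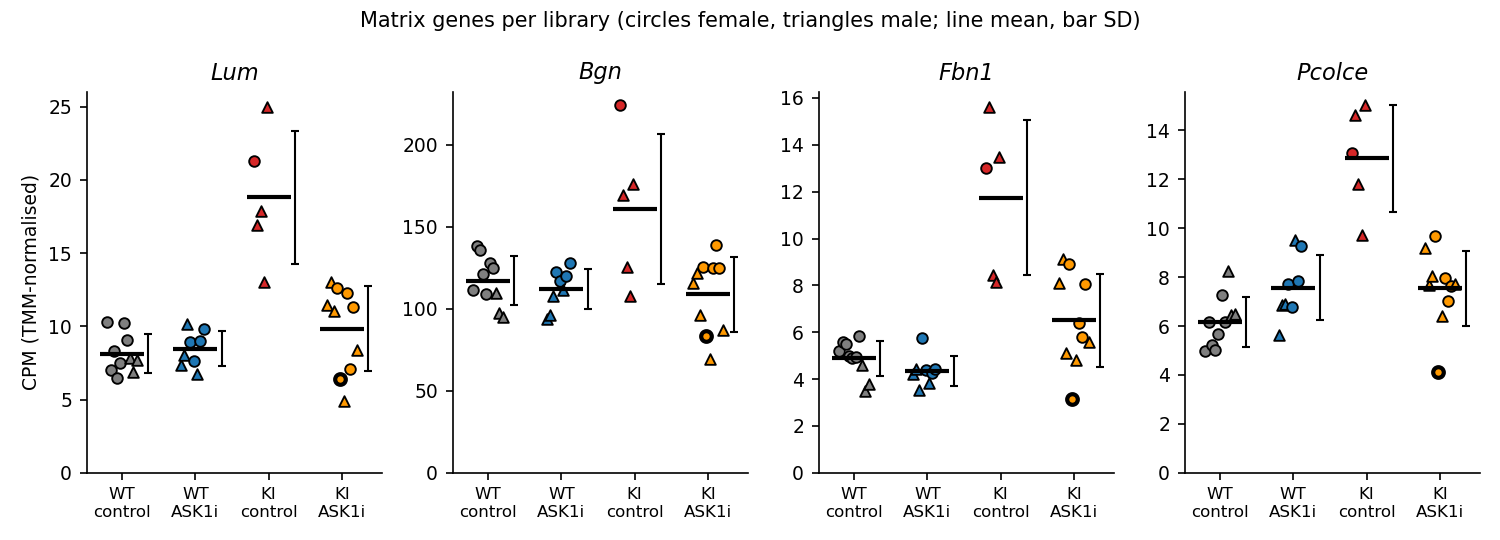
Lum, Bgn, Fbn1 and Pcolce in TMM-normalised CPM per library in the 4 groups (symbols as in the Nlrp3 figure). Lum averaged 18.8 ± 4.54 CPM in KI control and 9.85 ± 2.90 CPM in KI ASK1i.

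Of the matrix list 3 of 30 fell over all genes, Lum, Bgn and Fbn1, and 17 adjusted over the list alone (median -0.56, camera adjusted p = 6.05e-19, and adjusted p = 0.216 with an estimated correlation, and fry adjusted p = 0.0416). Col1a2, a chain of type I collagen, had a log2 fold change of -1.10 (SE 0.26) that did not pass (adjusted p = 0.160, 10 of 10 libraries below the KI control mean). Stellate cell markers had 0 of 16 called and 4 lower adjusted over the list alone (median -0.40, camera adjusted p = 1.52e-07, and adjusted p = 0.216 with an estimated correlation; fry adjusted p = 0.0438). Their median was -0.33 without the replicate 5 library, with 3 lower adjusted over the list alone, and fry no longer passed them (adjusted p = 0.0599). Without the replicate 5 library, the matrix median was -0.48 with 17 members lower adjusted over the list alone. The 8 genes kept their calls with log2 fold changes of -0.92 for Lum, -0.61 for Bgn, -0.81 for Fbn1, -0.70 for Pcolce, -0.68 for Col14a1, -0.72 for Rasa4, -0.43 for Sept8 and -1.57 for Eda2r.

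Camera placed other lists lower or higher in KI with the inhibitor although no member was called over all genes. Interferon-stimulated genes lay lower (0 of 21 called, 3 adjusted over the list alone; median -0.51, camera adjusted p = 4.64e-12, and adjusted p = 0.241 with an estimated correlation). Irf7 was at -0.60 (SE 0.19, adjusted p = 0.365) and Ifit2 at -0.69 (SE 0.22, adjusted p = 0.376), each below the KI control mean in 10 of 10 libraries. Adjusted over the list alone 0 passed with L code fitted (median -0.35). Cell cycle genes lay lower with 0 called, also adjusted over the list alone (median -0.53, camera adjusted p = 9.77e-09, and adjusted p = 0.338 with an estimated correlation). Cytokines and chemokines (median -0.47, camera adjusted p = 2.15e-06, and adjusted p = 0.338 with an estimated correlation) and markers of monocyte-derived macrophages (median -0.49, camera adjusted p = 3.11e-06, and adjusted p = 0.338 with an estimated correlation) lay lower with 0 called, also adjusted over the list alone. So did Kupffer cells (median -0.34, camera adjusted p = 4.29e-05, and adjusted p = 0.338 with an estimated correlation) and neutrophils (median -0.34, camera adjusted p = 0.000114, and adjusted p = 0.448 with an estimated correlation). T and NK cells (median -0.33, camera adjusted p = 0.000176, and adjusted p = 0.338 with an estimated correlation) and the inflammasome list (median -0.31, camera adjusted p = 0.000114, and adjusted p = 0.338 with an estimated correlation) lay lower with 0 called, also adjusted over the list alone. The apoptosis and necroptosis list, on cell death, did likewise (0 of 22; median -0.13, camera adjusted p = 0.00212, and adjusted p = 0.338 with an estimated correlation). Without the replicate 5 library the medians of the neutrophil and inflammasome lists were -0.18 and -0.19 (camera adjusted p = 0.00359 and 0.00202, and with an estimated correlation 0.440 and 0.314). With L code fitted the neutrophil median was 0.04 and camera placed the list upward without passing it (adjusted p = 0.927, from 3.96e-06 to 0.927 over the alternatives).

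Cholesterol synthesis lay higher in KI with the inhibitor (0 of 20 called over all genes, 11 adjusted over the list alone; median 0.61, camera adjusted p = 4.64e-12, and adjusted p = 0.338 with an estimated correlation). Adjusted over the list alone 0 passed with L code fitted (median 0.43), with the replicate block (0.51), in numbered titles (0.51), in males (0.49) and in females (0.84), and all 20 log2 fold changes were positive in each. Mvd (0.86, SE 0.27, adjusted p = 0.369) was above the KI control mean in 9 of 10 libraries and did not pass. PPARA targets (median 0.37, camera adjusted p = 0.000605, and adjusted p = 0.464 with an estimated correlation) and bile acid genes (median 0.30, camera adjusted p = 0.000627, and adjusted p = 0.338 with an estimated correlation) lay higher with 0 called, also adjusted over the list alone. Hepatocyte function (median 0.21, camera adjusted p = 0.00210, and adjusted p = 0.408 with an estimated correlation), the unfolded protein response (median 0.36, camera adjusted p = 0.00534, and adjusted p = 0.408 with an estimated correlation) and NRF2 targets (median 0.29, camera adjusted p = 0.00695, and adjusted p = 0.338 with an estimated correlation) lay higher with 0 called, also adjusted over the list alone. CAR and PXR targets had 2 higher adjusted over the list alone (median 0.38, camera adjusted p = 0.000578, and adjusted p = 0.338 with an estimated correlation) and lipogenesis 1 (median 0.35, camera adjusted p = 0.00280, and adjusted p = 0.356 with an estimated correlation). Me1 was at 0.95 (SE 0.26, adjusted p = 0.330, 10 of 10 libraries above the KI control mean). Without the replicate 5 library the medians were 0.16 for PPARA targets, 0.14 for bile acid genes, 0.12 for hepatocyte function, 0.21 for CAR and PXR targets, with 0 higher adjusted over the list alone, and 0.16 for lipogenesis. Camera still passed these 5 lists (adjusted p at most 0.0323, and at least 0.302 with an estimated correlation). With L code fitted camera placed lipogenesis downward without passing it (adjusted p = 0.860, from 2.03e-05 to 0.921 over the alternatives). Cyp1a2, of the AHR list that did not pass camera (adjusted p = 0.162, from 0.0364 to 0.386 over left-out libraries), was at 1.05 (SE 0.32, adjusted p = 0.365, 8 of 10 libraries above the KI control mean). The ASK1 cascade did not pass (median 0.03, adjusted p = 0.486), nor did acute-phase genes (median 0.04, adjusted p = 0.486, downward in camera), which without the replicate 5 library passed upward (median 0.18, adjusted p = 0.00202, and 0.314 with an estimated correlation). Single libraries ended 3 list calls: NRF2 without KI control replicate 1P (adjusted p from 0.000779 to 0.0620 over left-out libraries), lipogenesis without KI control replicate 1 (0.000282 to 0.0654) and the unfolded protein response without KI ASK1i replicate 3 (0.000111 to 0.0667). In total 19 of 33 lists passed camera, 8 upward and 11 downward, 0 with an estimated correlation (lowest adjusted p = 0.216) and 2 by fry, the matrix and stellate cell lists, of which the matrix list alone passed fry without the replicate 5 library. With L code fitted camera still passed the matrix, stellate cell, interferon, cell cycle, cholesterol, PPARA and bile acid lists, and the other 12 lost their calls. Median, mean and camera direction differed in sign for the acute-phase, cholangiocyte and adipocyte lists, none of which passed.

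The count of 8 genes depended on single libraries. It was 0 in edgeR without KI control replicate 1, 2 or 1P or KI ASK1i replicate 3, 6, 1P or 4P, where 889 to 1443 genes had an unadjusted p under 0.05, against 1539 with all libraries. It was 14 without KI ASK1i replicate 2, 12 without replicate 5, 3 to 5 without KI ASK1i replicate 2P or 3P, any WT control library or any WT ASK1i library other than replicate 3, and 6 to 12 without each of the remaining ones. Over left-out libraries the adjusted p of Lum ran from 0.00954 to 0.293, that of Bgn from 0.00855 to 0.285 and that of Pcolce from 0.00996 to 0.285. The calls of Fbn1, Rasa4 and Sept8 each ended without any of 26 single libraries (highest adjusted p = 0.479, 0.285 and 0.285) and that of Col14a1 without any of 27 (highest 0.479). DESeq2 called 37 genes and limma-voom 8, while edgeR called 0 with L code fitted, among numbered titles alone and in either sex alone (519 to 2006 genes with an unadjusted p under 0.05 over the 8 settings that gave 0). With L code as a covariate the matrix median was -0.48 with 4 members lower adjusted over the list alone, and in males alone it was -0.42 with 5. With sex fitted within genotype, chosen after seeing the data, it was -0.54 with 18.

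The interaction asks whether the inhibitor acted differently in KI and in WT liver. No gene passed in edgeR (smallest adjusted p = 0.0623), with 1251 genes at an unadjusted p under 0.05 where 746.7 would be expected by chance. DESeq2 called 16 genes, limma-voom 2 and limma-voom with quality weights 6. The smallest p belonged to Pcolce, whose log2 fold change with the inhibitor was -0.77 in KI and 0.27 in WT (difference -1.04, SE 0.19, adjusted p = 0.0623). Next to it was Islr, a protein of mesenchymal cells (-0.73 and 0.42, difference -1.14, SE 0.21, adjusted p = 0.0623). Differences that did not pass were -1.05 for Lum (SE 0.24, adjusted p = 0.317), -3.63 for Sult1e1 (SE 0.77, 0.209), -1.08 for Hmgcs1 (SE 0.35, 0.460), 1.45 for Lrrc16a (SE 0.29, 0.137), 1.82 for Cyp7b1 (SE 0.50, 0.365), -0.49 for Nlrp3 (SE 0.32, 0.698) and 0.13 for Map3k5 (SE 0.21, 0.899). The fall of matrix genes in KI and the rise of cholesterol genes in WT were not shown gene by gene to differ between the genotypes. By list, camera placed the matrix list lower in KI than in WT (median difference -0.56, 13 members lower adjusted over the list alone, camera adjusted p = 6.15e-11, and adjusted p = 0.410 with an estimated correlation). It placed cholesterol synthesis likewise (-0.82, 12 members lower, camera adjusted p = 2.32e-14, and adjusted p = 0.410 with an estimated correlation). With L code fitted, in males and in numbered titles 0 members of either list passed adjusted over the list alone (matrix medians -0.42, -0.43 and -0.56, cholesterol medians -0.66, -0.44 and -0.79). In females 5 matrix members passed (-0.88) and 0 cholesterol members (-0.69). Camera passed 14 of 33 lists, 5 upward and 9 downward, of which 0 passed with an estimated correlation (lowest adjusted p = 0.410) or by fry. The acute-phase list passed upward without the replicate 5 library (adjusted p = 2.10e-07, and 0.283 with an estimated correlation). Median, mean and camera direction differed in sign for the neutrophil (0.65), CAR and PXR, AHR, lipogenesis, cholangiocyte, adipocyte and circadian lists, none of which passed. Some left-out libraries gave called genes. The count was 1 without WT control replicate 5, WT ASK1i replicate 6 or KI ASK1i replicate 4, 2 without WT control replicate 8, WT ASK1i replicate 2, KI control replicate 4 or KI ASK1i replicate 5, and 3 without KI ASK1i replicate 1, Pcolce and Islr among them. Over left-out libraries the adjusted p of Pcolce ran from 0.0199 to 0.294 and that of Islr from 0.0199 to 0.285.

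The inhibitor's effects in WT and in KI were also compared over genes. Of the 209 genes changed in WT, 169 (80.9%) had the same sign in KI, against 56.4% of all tested genes, and 56 of them had that sign with an unadjusted p under 0.05 in KI. Movement against the KI change was measured by the covariance over genes of the KI effect on control chow and the diet effect in KI. It was -0.286, with a correlation of -0.539. Both effects use the 5 KI control libraries. Unchanged simulated groups gave a covariance of -0.0593 and a correlation of -0.679 (from -0.703 to -0.643). They held no KI effect, so the correlations cannot be compared. With those libraries split between the 2 effects the covariance averaged -0.246 over 20 fits (from -0.294 to -0.164) and the correlation -0.384 (from -0.448 to -0.266). Without the replicate 5 library the covariance was -0.135 with shared controls and -0.0935 with split controls (from -0.141 to -0.0220). Genes are not independent replicates, so these values carry no p.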

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

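The tests of a swap with a WT library, of the matrix list without 1 library and within each sex, of the cholesterol list in L6 with sex in the fit, and of other splits of the samples were chosen after the result was seen, and the others were set down before. The library labelled KI ASK1i replicate 5 lay among the WT libraries on the first principal component (gap over range 0.702). It held 0.0559 of the KI effect, where the other 9 KI ASK1i libraries held 0.857 to 1.17. A mixture of KI and WT RNA was excluded, since the median share of the KI rise over neutrophil markers was -0.00112. A swap needs a WT library on the KI side of that component, of which there were 0. A wrong label on a WT control library or an uninduced KI allele stayed open, as values disagreed. Replicate 5 scored 6.32 for cholesterol synthesis, within WT control (4.98 to 7.07) and below WT ASK1i (6.99 to 7.83). Its Sult1e1 (30.4 CPM) exceeded WT control (highest 3.22).

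Matrix genes were lower in KI on the inhibitor than in KI on control chow. Replicate 5 as the whole source was excluded, since the list median without it was -0.48 with 17 members lower adjusted over the list alone, and so was a weaker response of all genes, which predicts -0.0658. Uneven sexes stayed open. In males alone the bound was missed, with exact two-sided p = 0.0714 over 126 splits (median -0.42). With diet permuted within each sex, set after that, p was 0.0251 over 756 splits, and without replicate 5 0.0111 over 630. That test holds 1 KI control female, of the highest matrix score. An effect of the inhibitor on matrix-producing cells is a hypothesis that these data may fit. A batch marked by L code was not excluded: with L code as a covariate the median was -0.48 with 4 lower adjusted over the list alone, and without replicate 5, chosen after seeing the data, -0.50 with 12 lower adjusted over the list alone.

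Cholesterol synthesis genes were higher in WT on the inhibitor. A batch marked by L code was not excluded. Among the L6 libraries, with sex in the fit, the list median was 1.10. Adjusted over the list alone 17 of 20 members were higher, and over all genes 0. The permutation test set before ignored sex, and within sex its p could not fall below 0.0625. With L code as a covariate the median was 1.11 with 18. Uneven sexes were excluded, with medians of 0.98 in males and 1.63 in females. An effect of the inhibitor diet on sterol synthesis in WT liver is a hypothesis, found and tested on the same data.

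Among 80 group values tested for a library apart from its group, 14 passed, 10 of them at KI ASK1i replicate 5, where chance gives about 1 in 20. As the gap to the nearest library over the group's range, that library was lowest for Nlrp3 (0.580), Saa2 (0.843), Lcn2 (0.906), S100a8 (0.705), Timp4 (0.823), Timp1 (0.533), Sult1e1 (0.774) and C6 (0.734) and highest for Cyp8b1 (0.612). WT ASK1i replicate 5 was highest for Nlrp3 (0.650) and Fbn1 (0.536), WT control replicate 8 highest for Timp4 (0.575) and WT control replicate 1P lowest for Cyp8b1 (0.499).

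The diet effect in KI minus that in WT passed camera for 14 lists, with 0 passing at an estimated correlation (adjusted p at least 0.410). The median differences were -0.56 for matrix, -0.40 for stellate cell, -0.34 for monocyte-derived macrophage, -0.28 for cytokine, -0.13 for apoptosis, -0.82 for cholesterol, -0.47 for cell cycle, -0.48 for interferon and -0.39 for female-biased genes. They were 0.45 for the unfolded protein response, 0.52 for PPARA targets, 0.26 for hepatocyte function, 1.88 for male-biased and 0.94 for erythroid genes. Calls ended for the macrophage list without WT control replicate 2P, KI control replicate 1 or KI ASK1i replicate 5 (adjusted p up to 0.0970, lowest 0.00258). They ended for cytokines without KI ASK1i replicate 5 (0.00110 to 0.0936), for female-biased genes without WT control replicate 8 (0.00137 to 0.0755) and for hepatocyte function without any of 5 libraries (0.00258 to 0.187). Of the 14 only the matrix and cholesterol lists kept their call under every other covariate, filter and subset of libraries. Without KI ASK1i replicate 5 the medians were 0.32 for PPARA targets, 0.16 for hepatocyte function, 1.04 for male-biased and -0.68 for female-biased genes. With L code fitted camera gave the other direction, without passing, for macrophage (adjusted p = 0.279; 0.00258 to 0.925 over the alternatives), apoptosis (0.997; 0.000749 to 0.997), cell cycle (0.942; 7.69e-09 to 0.942) and PPARA genes (0.942; 8.80e-07 to 0.942). The sex difference differed between WT and KI for 1 gene, Mup11, of a family with shared reads (male minus female log2 4.93 in WT and -6.62 in KI, adjusted p = 0.0439). It differed for 0 without KI ASK1i replicate 5, where 1466 genes had an unadjusted p under 0.05 in edgeR.

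Other splits of the same libraries were refitted, 41 splits per comparison with the real one. No other split gave as many genes for KI against WT on control chow (8466, highest other 1445). Nor did any on the ASK1i diet (8819, highest other 2252) or for the inhibitor in WT (209, highest other 0). A share of 1 in 41 is the lowest possible, and a batch was not tested. For KI against WT the other splits mix genotypes within groups. For the inhibitor in KI 8 of 41 splits gave 8 genes or more (highest other 976), so chance or an untested structure stayed open. The interaction's real count of 0 is reached by any split (highest other 1) and decides nothing.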

How the results depend on the processing

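Settings chosen after seeing the data are listed above. No named gene reversed. For KI against WT on control chow 1680 of 1743 values of named genes stayed past the threshold, on the ASK1i diet 669 of 674, and in KI with the inhibitor 100 of 199. With the inhibitor in WT 499 stayed and 202 did not. The cause was not tested for the changes below, except that subsets hold fewer libraries. The 8466 genes of KI against WT on control chow became 5103 with sex and L code, 3686 in females (where KI control is 1 library, assumed to vary like the others) and 5341 in females without replicate 5. They were 7386 to 8926 over left-out libraries. The 8819 on the ASK1i diet became 5712 in females (8371 to 9435). The 209 genes of the inhibitor in WT became 365 with DESeq2, 826 with limma-voom and quality weights, 23 with sex and L code, 7.0e+02 (to 2 digits, 491 higher and 210 lower) with only the 2 groups, 19 in numbered titles, 8 in females. By edgeR they were 0 in males and 0 in L6 (644 and 962 at an unadjusted p under 0.05). Without replicate 5 they were 673 with DESeq2, 395 with limma-voom, 43 with sex and L code, 466 with sex within genotype and 77 in females. They ran from 101 to 375 over left-out libraries. The 8 genes of the inhibitor in KI became 4 with RLE, 37 with DESeq2, 18 with quality weights, 4 with title set alone, 3 with no covariate. They were 0 by edgeR with sex and L code, the replicate block, only the 2 groups, numbered titles, males, females or sex within genotype (519 to 2006 at an unadjusted p under 0.05). Without replicate 5 they were 27 with DESeq2, 15 with limma-voom, 2 with the block, 0 with sex and L code and 5 in females. They ran from 0 to 14 over left-out libraries. The interaction's 0 genes became 16 with DESeq2, 2 with limma-voom, 6 with quality weights and 1 with title set alone. Without replicate 5 they were 48 with DESeq2, 2 with limma-voom, 2 with sex alone, 3 with sex within genotype and 7 in females. They ran from 0 to 3 over left-out libraries.

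Pairing by replicate number stayed open, with no other pairs compared. Deviations of same-numbered libraries correlated over 0.1 in 3 of 5 KI and 3 of 8 WT pairs. Between genotypes 2 of 5 did on control chow and 3 of 7 on ASK1i. With the block 7493 genes changed between KI and WT on control chow and 8202 on ASK1i. It was 133 for the inhibitor in WT, and 0 in KI and the interaction.

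The covariance of the KI effect and the diet effect in KI, -0.286, was -0.387 with DESeq2, -0.196 with quality weights, -0.426 with no filter, -0.247 with at least 1 CPM, -0.0787 with sex and L code, -0.220 with the replicate block. It was -0.186 with only the groups compared, -0.337 in numbered titles, -0.134 in males, -1.06 in females, -0.201 with sex within genotype, -0.246 with split controls and -0.232 with a prior count of 2. Without replicate 5 it was -0.136 with DESeq2, -0.142 with limma-voom, -0.146 with sex alone, -0.129 with the block, -0.105 with sex and L code, -0.135 with sex within genotype, -0.572 in females and -0.0935 with split controls. It ran from -0.378 (without KI ASK1i replicate 2) to -0.134 (without replicate 5, with the count filter rerun) over left-out libraries.

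Of 165 list tests 84 passed camera (80 to 87 over left-out libraries), 1 with an estimated correlation and 53 by fry. It was 3 with an estimated correlation without replicate 5. Lists were not run with DESeq2 or limma-voom. List directions that reversed are given with adjusted p and, in brackets, its range over all alternatives. In KI with the inhibitor they were neutrophil markers with sex and L code 0.927 (3.96e-06 to 0.927), lipogenesis with sex and L code 0.860 (2.03e-05 to 0.921), female-biased genes in females without replicate 5 0.00319 (0.00319 to 0.946). Acute-phase genes did so with sex and L code 0.00892, without replicate 5 0.00202, and without it with sex alone 0.00148, the block 0.00166, sex and L code 0.000198, sex within genotype 0.00810 and in females 0.000686 (0.000198 to 0.977). In WT they were matrix genes in females without replicate 5 0.0447 (0.0447 to 0.974). PPARA targets did so with sex and L code 0.00744, in males 0.0234 and in L6 0.000553 (0.000553 to 0.949). In the interaction, with sex and L code, they were neutrophil 0.000189 and, without replicate 5, 0.00049 (0.000189 to 0.979), Kupffer cell 0.00300 (0.00300 to 0.988), macrophage 0.279 (0.00258 to 0.925), apoptosis 0.997 (0.000749 to 0.997), PPARA 0.942 (8.80e-07 to 0.942) and cell cycle 0.942 (7.69e-09 to 0.942). AP-1 genes did so in females 0.0323 (0.0323 to 0.997) and hepatocyte function in females without replicate 5 0.848 (0.00258 to 0.997). Depth limited genes at 0 to 3 counts over a group, whose folds are bounds or ratios with counting intervals.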

Other observations

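The check of slopes with genes picked in 1 WT group and measured in the other was chosen after the result was seen; the slope test was written before. Cyp4a12a, a fatty acid hydroxylase of male liver, averaged 37.3 CPM in WT males and 0.157 in WT females, and 1.95 and 0.309 in KI. Cyp2d9, a steroid hydroxylase of male liver, averaged 419.7 CPM in WT males and 85.8 in WT females, and 607 and 332 in KI. In WT the male minus female log2 differences of 8.02 (adjusted p = 2.81e-05) and 2.39 (adjusted p = 0.000337) passed in edgeR. In KI 2.93 (adjusted p = 0.4003) and 0.84 (adjusted p = 0.502) did not. Cyp3a41a, a female-biased copy with shared reads, averaged 602 CPM in WT males and 2288 in WT females, and 0.993 and 102 in KI. It passed in KI (-6.86, adjusted p = 0.0212) and not in WT (-3.16, adjusted p = 0.219). The differences between the genotypes did not pass for these 3 genes (adjusted p = 0.414, 0.369 and 0.593). The male-biased list had a median male minus female log2 difference of 2.39 in WT (10 of 14 called) and 0.57 in KI (2 called; without KI ASK1i replicate 5, 1.02 and 1 called). The female-biased list had -1.12 in WT (1 of 18 called) and -2.51 in KI (7 called; without KI ASK1i replicate 5, -2.04 and 3 called).

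A hypothesis was that KI livers lose sex-biased expression. Over the 544 autosomal genes that differed between the sexes in WT without KI ASK1i replicate 5, the slope of the KI difference on the WT one was 0.227. It was 0.136 over 258 with it. Genes are not independent replicates. Genes picked for a large WT difference shrink in any new group: 48 autosomal genes picked in WT control had a slope of 0.359 in WT ASK1i and 0.199 in KI. The 88 picked in WT ASK1i had 0.576 in WT control and 0.0546 in KI. The lower slope in KI may therefore come in part from that choice, and the hypothesis stayed open.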
